A study of Homo sapiens with 24 samples.

How the data were processed

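The deposited files hold raw gene counts, in 1 table for the libraries without RA and 1 for those with RA; per the submitters' processing notes, reads of a directional poly(A) kit were trimmed with Trimmomatic, aligned to hg19 with HISAT2 and counted with HTSeq, and DESeq2 was used for their tests, with no versions stated. The strand setting of the counting and the annotation release are not stated, so the counts of genes that overlap a gene on the other strand, or that share sequence with copies (histone genes, FUT3, SLC2A14, pseudogenes), are uncertain. All 24 libraries were used, with 10526988 to 16395091 counts each. Of 57820 gene identifiers per table, 47 second copies of pseudoautosomal genes (282 counts) were left out, 51996 were matched to a symbol, and 932 whose symbol is shared were kept by identifier.

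Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Knockdowns, the 2 single knockdowns against each other and departures from additivity were tested in 1 fit per RA state (12 libraries), RA and its interactions in 1 fit of 24 libraries. Genes were filtered with filterByExpr, libraries scaled with TMM, and genes tested with edgeR's robust quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Departure from additivity is the double-knockdown effect minus the sum of the single effects. DESeq2 1.42.0 served as the second tool. Groups, tests, gene lists, the rule for named genes and most alternative analyses were fixed before the data were examined.

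The 37 gene lists hold 971 entries, 956 of them found in the tables. They cover pluripotency, neural progenitor, proneural, neuronal, HOX, retinoid, Notch, Wnt, TGF-beta and BMP, extracellular matrix, DNA replication, mitotic, p53, amino acid and ER stress, interferon, glycolysis, oxidative phosphorylation, mitochondrial DNA, ribosomal protein, ribosome biogenesis, replication-dependent histone, microRNA processing, microRNA host, splicing factor, DEAD-box, REST, cholesterol and hypoxia genes. Markers of neural crest, mesoderm, endoderm, trophoblast, astroglia, oligodendrocytes, smooth muscle and fibroblasts, and epithelium, and nuclear noncoding and immediate early genes that respond to RNA handling, complete them. Messages of replication-dependent histones normally lack a poly(A) tail, so their counts in these poly(A) libraries may not follow total histone RNA. Lists were tested with camera at a preset correlation of 0.0100, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. A count "adjusted over the list alone" takes the same gene p-values with the adjustment limited to the list.

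The rule for named genes takes DDX5 and DDX17. It takes the 6 genes with the largest rise and the 6 with the largest fall against siCtrl (4 each for the other comparisons) among those past the threshold, with a symbol, a mean log2 CPM of at least 2 and, for 2 groups, no overlap between their libraries. It adds the 3 smallest p per direction, up to 4 members of a list with the smallest p, and any member of a count of 5 or fewer. The text leaves out some genes withheld for evaluation, genes without a symbol and, for length, part of the list members, a choice made after the values were seen; CTSD, C19orf48P and OAF were named after their values were seen, as neighbours.

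Replicate numbers are not said to mark shared cultures. In residuals of each fit, libraries with the same number had a median correlation of 0.340 without RA and 0.362 with RA, against -0.199 and -0.173 for different numbers, and every pair passed 0.1 for siDDX5 in both states, the double knockdown without RA and siDDX17 against siDDX5 with RA. For those the result with the replicate number as a block is given beside the unblocked one. Replicate 2 of every group was highest on the first component within groups (35.2% of variance without RA, 54.9% with RA). With RA, siDDX17 replicate 1 stood apart. Fits of replicates 1 and 3 alone, with a replicate 2 term and without the library labelled siDDX17 replicate 1 came after seeing the data. No 2 libraries of a group were duplicates, by counts that differed by more than sampling.

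The analysis was tested on simulated data built from these counts: for siDDX5 without RA, 70.6% of genes changed 2-fold and 89.9% of those changed 4-fold were called, with 7 false calls; with RA 52.5% and 90.8%, with 4; for the double-knockdown interaction 23.7% and 70.5%, with 1. The shifted list was called and 0 of 36 random lists were. Simulated genes varied independently of each other, so this does not test list calls where members vary together. Shared controls were checked against 20 simulations, as 3 control libraries cannot be halved. Gene neighbours come from the gene order of GENCODE 29, whose build differs from the authors'. Splicing, exon usage and raw reads were not analysed here.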

Results

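The libraries hold poly(A) RNA of NTERA2 human embryonal carcinoma cells, kept without retinoic acid (RA) or cultured with 10 µM RA for 14 days. Each state has 4 groups of 3 libraries, taken 60 h after transfection with a non-targeting siRNA (siCtrl), siDDX5, siDDX17 or both siRNAs. DDX5 and DDX17 are closely related DEAD-box RNA helicases. Values after ± are standard errors of log2 fold changes, or standard deviations for levels in CPM (counts scaled by library size), with n = 3 libraries per group throughout. "Rose" and "fell" mean an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a fit of the 12 libraries of that state. The labels do not say whether the replicates are separate cultures, so every p-value measures only the spread between these samples.

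DDX5 RNA stood at 575 ± 37.05 CPM in siCtrl cells without RA and 567 ± 35.2 CPM with RA. DDX17 stood at 523 ± 23.1 and 625 ± 47.2 CPM. siDDX5 left 26.7 ± 0.351% of control DDX5 without RA and 33.1 ± 0.543% with RA. Both siRNAs together left 32.1 ± 1.04% and 31.0 ± 4.92%. siDDX17 left 35.2 ± 14.2% of control DDX17 without RA and 21.4 ± 2.58% with RA. Together the siRNAs left 31.1 ± 2.12% and 34.5 ± 3.37%. The helicase not targeted by a single siRNA did not pass the test in either state. DDX17 stood at 115 ± 12.3% and 97.4 ± 13.2% of control after siDDX5. DDX5 stood at 81.8 ± 29.5% and 85.9 ± 11.3% after siDDX17. The library labelled siDDX17 replicate 1 without RA stood apart from its group, with DDX5 at 280 CPM against 605 and 527 CPM in the other siDDX17 libraries. Its DDX17 was at 269 against 149 and 134 CPM.

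**Figure D1:**
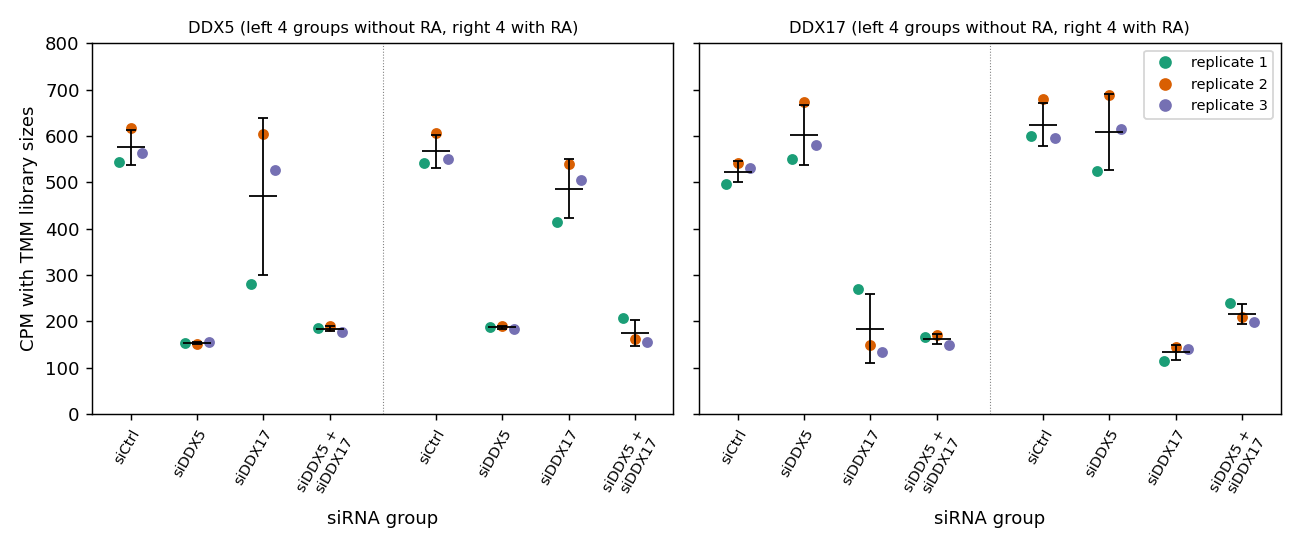
DDX5 and DDX17 in each of the 24 libraries, in CPM with TMM library sizes; bars give mean ± SD of the 3 libraries of a group.

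In siCtrl cells, pluripotency genes were lower and HOX and neural genes higher with RA than without. 5871 genes rose and 5619 fell among 18882 tested in the fit of all 24 libraries, 3766 and 2835 of them by at least 2-fold. NR2F1, a nuclear receptor of the developing brain, HOXA3 and its antisense RNA HOXA-AS2 were listed at 0 counts without RA and were at least 2220-, 1630- and 770-fold higher with RA, taking 3 counts per group as the floor. The fibrillar collagen genes COL3A1 (7963-fold (counting interval 3864 to 19806)) and COL2A1 (8.10 ± 0.19) rose. The transcription factors ZIC1 (6.88 ± 0.16) and ZNF503 (8.51 ± 0.21) rose as well. The noncoding RNAs of pluripotent cells LINC-ROR and LINC00678, and D21S2088E, were at least 429-, 335- and 1039-fold lower with RA, where they were listed at 0. ESRG (-11.32 ± 0.44), the deubiquitinase USP44 (-7.68 ± 0.14), the kinase PIM2 (-4.65 ± 0.11) and the pluripotency factor ZSCAN10 (-10.82 ± 0.27) fell. DDX5 (-0.17 ± 0.18, adjusted p = 0.440 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and DDX17 (0.11 ± 0.18, adjusted p = 0.608) themselves did not pass. The libraries with and without RA were counted in separate tables and no label rules out a batch that coincides with RA. With replicates 1 and 3 alone 10579 genes passed.

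All 24 measured pluripotency genes fell (median log2 fold change -6.68 with genes at 0 set to their bound, camera adjusted p = 1.7e-17, adjusted p = 1.2e-05 with an estimated correlation). L1TD1 (-5.89 ± 0.15) and GDF3 (-8.00 ± 0.24) were among them. Of 29 HOX genes, 28 rose and 1 fell (median 6.97 with bounds, camera adjusted p = 6.8e-17, adjusted p = 0.00118 with an estimated correlation). HOXB9 stood at 7.64 ± 0.22. Retinoid receptor, metabolism and target genes rose in 13 and fell in 4 of 21 cases (camera adjusted p = 0.00460, adjusted p = 0.0216 with an estimated correlation). MEIS1 (8.33 ± 0.22) and the retinol dehydrogenase RDH10 (5.21 ± 0.22) led the rises. Neural progenitor markers rose in 16 of 25 cases and fell in 5 (camera adjusted p = 0.00163, adjusted p = 0.0451 with an estimated correlation), with OTX2 at -7.20 ± 0.29. Proneural factors rose in 19 of 26 and fell in 4 (camera adjusted p = 5.1e-04, adjusted p = 0.0216 with an estimated correlation). POU4F1 (5.04 ± 0.31) and EBF1 (2.73 ± 0.18) were among the former. Neuronal cytoskeletal and synaptic genes rose in 25 of 40 and fell in 9 (camera adjusted p = 2.0e-04, adjusted p = 0.0208 with an estimated correlation). The synaptic genes SYT4 (6.81 ± 0.32) and SNAP25 (5.49 ± 0.28) rose. Neuronal genes known as targets of the repressor REST rose in 17 of 32 and fell in 6 (camera adjusted p = 0.00799, adjusted p = 0.158 with an estimated correlation).

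Lists of other lineages and of signalling pathways rose, fell or did not pass. Neural crest markers rose in 12 of 16 cases and fell in 3 (camera adjusted p = 5.0e-04, adjusted p = 0.0216 with an estimated correlation), with SNAI2 at 4.34 ± 0.18. Astrocyte and radial glia markers rose in 7 of 13 and fell in 2 (camera adjusted p = 0.00799, adjusted p = 0.0347 with an estimated correlation), with the glutamate transporter SLC1A3 at 4.40 ± 0.18. Extracellular matrix genes rose in 25 of 30 (camera adjusted p = 1.2e-10, adjusted p = 0.0516 with an estimated correlation). Smooth muscle and fibroblast markers rose in 11 of 15, with 3 lower (camera adjusted p = 0.00708, adjusted p = 0.217 with an estimated correlation). Targets of TGF-beta and BMP rose in 18 of 23 and fell in 3 (camera adjusted p = 5.5e-05, adjusted p = 0.190 with an estimated correlation). Wnt targets rose in 15 of 19 (camera adjusted p = 6.6e-07, adjusted p = 0.0208 with an estimated correlation), led by APCDD1 (4.69 ± 0.14). Epithelial markers fell in 13 of 16 and rose in 1 (camera adjusted p = 2.9e-05, adjusted p = 0.0851 with an estimated correlation), with the tight junction gene CLDN6 at -4.30 ± 0.15. Lists that did not pass held members moving both ways (rose/fell of measured): Notch 14/4 of 22 (camera adjusted p = 0.0653), mesoderm 7/3 of 14 (camera adjusted p = 0.479) and endoderm 3/2 of 8 (camera adjusted p = 0.354). The same was seen for trophoblast 6/3 of 9 (camera adjusted p = 0.266) and oligodendrocyte 2/4 of 7 (camera adjusted p = 0.343).

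DNA replication, mitotic, ribosome biogenesis and glycolysis genes fell with RA. DNA replication genes fell in 29 of 34 cases (camera adjusted p = 5.0e-10, adjusted p = 0.0208 with an estimated correlation). Mitotic genes fell in 33 of 36 (camera adjusted p = 2.4e-09, adjusted p = 0.0216 with an estimated correlation). CCNE1 stood at -1.85 ± 0.12 and AURKA at -1.27 ± 0.10. Ribosome biogenesis factors fell in 31 of 37 (camera adjusted p = 1.2e-10, adjusted p = 0.0216 with an estimated correlation). Ribosomal proteins fell in 54 of 55 (camera adjusted p = 1.2e-08, adjusted p = 0.427 with an estimated correlation), as did other DEAD-box helicases in 14 of 26 (camera adjusted p = 0.00477, adjusted p = 0.0332 with an estimated correlation). Glycolysis genes fell in 18 of 24 and rose in 2 (camera adjusted p = 1.4e-06, adjusted p = 0.0216 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 24 of 41 (camera adjusted p = 4.2e-04, adjusted p = 0.427 with an estimated correlation). Amino acid and ER stress genes fell in 20 of 33 and rose in 5 (camera adjusted p = 7.3e-05, adjusted p = 0.0332 with an estimated correlation). Splicing factors fell in 25 of 43 and rose in 7 (camera adjusted p = 0.00320, adjusted p = 0.248 with an estimated correlation), with MBNL1 (1.57 ± 0.17) and NOVA1 (1.64 ± 0.18) among those that rose. Targets of p53 rose in 19 of 32 and fell in 1 (camera adjusted p = 0.00708, adjusted p = 0.537 with an estimated correlation). Immediate early and nuclear noncoding genes, which also track RNA handling, rose in 7 of 14 (camera adjusted p = 0.0164, adjusted p = 0.427 with an estimated correlation). Lists that did not pass were (rose/fell of measured) interferon-stimulated genes 16/7 of 31 (camera adjusted p = 0.136) and hypoxia 7/10 of 21 (camera adjusted p = 0.479). Cholesterol genes 2/4 of 24 (camera adjusted p = 0.346) and replication-dependent histones 2/1 of 13 (camera adjusted p = 0.973) did not pass either. The same held for genes of mitochondrial DNA 0/1 of 13 (camera adjusted p = 0.136), microRNA processing 5/7 of 20 (camera adjusted p = 0.212) and microRNA hosts 7/5 of 13 (camera adjusted p = 0.191). LIN28A stood at -8.25 ± 0.26 and MIR100HG at 6.45 ± 0.32.

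After siDDX5 without RA, DDX5 itself (-1.91 ± 0.21) and GNPAT (-0.87 ± 0.11), an enzyme of ether lipid synthesis, fell, with adjusted p = 0.00542 and 0.0230 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No gene rose among 16852 tested, 572 had an unadjusted p under 0.05, and DESeq2 called 6 genes. No member of the 4 lists called by camera passed the test. Targets of p53 had a median of 0.22 (camera adjusted p = 0.00785, adjusted p = 0.976 with an estimated correlation, fry adjusted p = 0.993), with the cyclin gene CCNG1 at 0.25 ± 0.10. Amino acid and ER stress genes had a median of 0.10 (camera adjusted p = 0.0228, adjusted p = 0.668 with an estimated correlation, fry adjusted p = 0.656). Splicing factors stood at -0.08 (camera adjusted p = 0.00165, adjusted p = 0.668 with an estimated correlation, fry adjusted p = 0.656). REST targets stood at -0.08 (camera adjusted p = 0.0452, adjusted p = 0.668 with an estimated correlation, fry adjusted p = 0.656), and among them VGF, a secreted neuropeptide precursor, at -0.53 ± 0.11. Leaving out any 1 of siCtrl replicates 1, 2 and 3 or siDDX5 replicate 2 left 1 gene. Without siDDX5 replicate 1 or 3 the count was 0, and replicates 1 and 3 alone gave 0. Stress genes (3 of 6, highest camera adjusted p = 0.208) and REST targets (4 of 6, highest camera adjusted p = 0.262) lost their call in fits with 1 library left out. With the replicate number as a block 2 genes passed, and REST targets lost their call (camera adjusted p = 0.0916).

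After siDDX5 with RA, DDX5 (-1.59 ± 0.14, 3.02-fold lower) and SLC2A14 (-1.11 ± 0.14, 2.16-fold lower), a glucose transporter whose sequence closely resembles SLC2A3, fell. Their adjusted p values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 7.7e-04 and 0.0174. No gene rose among 17810 tested, 737 had an unadjusted p under 0.05, and DESeq2 called 16, 7 of them higher. GNPAT stood at -0.59 ± 0.10, SLC2A3 at -0.59 ± 0.15 and MIR130AHG, a microRNA host transcript, at 0.61 ± 0.11. Camera called 8 lists with no member past the test. The lists with higher medians were ribosomal proteins (0.21, camera adjusted p = 2.1e-04, adjusted p = 0.717 with an estimated correlation), HOX genes (0.12, camera adjusted p = 0.0204, adjusted p = 0.528 with an estimated correlation) and oxidative phosphorylation (0.15, camera adjusted p = 0.0211, adjusted p = 0.717 with an estimated correlation). Also higher were replication-dependent histones (0.38, camera adjusted p = 0.0211, adjusted p = 0.528 with an estimated correlation) and immediate early and nuclear noncoding genes (0.22, camera adjusted p = 0.0211, adjusted p = 0.528 with an estimated correlation), with FOS at 0.64 ± 0.16. Those with lower medians were epithelial markers (-0.22, camera adjusted p = 0.00137, adjusted p = 0.124 with an estimated correlation), cholesterol genes (-0.15, camera adjusted p = 0.0348, adjusted p = 0.310 with an estimated correlation) and genes of mitochondrial DNA (-0.28, camera adjusted p = 0.0355, adjusted p = 0.717 with an estimated correlation). Without siCtrl replicate 2 none of the lists with higher medians was called (camera adjusted p = 0.210, 0.260, 0.372, 0.0685 and 0.168 in that order). Only epithelial markers kept their camera call in every leave-out. Leaving out any 1 of the 6 libraries (siCtrl or siDDX5 replicates 1, 2 and 3) left 1 gene and replicates 1 and 3 alone gave 0. With the replicate number as a block, used here because the replicates paired by number, 13 genes passed, 4 higher and 9 lower. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in that fit, GNPAT (adjusted p = 0.00619) and SLC2A3 (adjusted p = 0.00690) were lower and MIR130AHG (adjusted p = 0.0305) higher. Camera with the block also called p53 targets, with a median of -0.08 (camera adjusted p = 0.0714, with the block 0.0482).

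After siDDX17 without RA, 58 genes rose and 129 fell. Which side is larger depends on the fit: no filter gave 863 higher and 734 lower, leaving out siDDX17 replicate 2 or 3 424 and 377 or 456 and 365, and all 24 libraries 374 and 380. The largest rises were IFITM10 (4.57 ± 0.75), SMIM47 (3.79 ± 0.61), BCAN-AS1 (3.43 ± 0.76), ESPNL (2.85 ± 0.37) and LEMD1 (2.19 ± 0.34). Without the library labelled siDDX17 replicate 1 they stood at 3.02, 2.66, 1.66, 2.29 and 1.52, and BCAN-AS1 did not pass. The cytokine gene IL16 (4.27 ± 0.54) was among those with the smallest p. The largest falls were MIR210HG, the host transcript of miR-210 (-1.96 ± 0.36), PTPRCAP (-1.78 ± 0.31) and DDX17 (-1.50 ± 0.20). Large falls were also seen for the trafficking gene TRAPPC6A (-1.46 ± 0.19), D2HGDH, which oxidizes D-2-hydroxyglutarate (-1.44 ± 0.17), and RHPN1 (-1.41 ± 0.29), beside TMEM129 (-1.34 ± 0.14) and the translation factor EIF2D (-1.14 ± 0.13). Targets of p53 had the highest median of the lists, 0.96 (camera adjusted p = 2.2e-10, adjusted p = 0.801 with an estimated correlation, fry adjusted p = 0.290). 1 of 32 rose, 27 when adjusted over the list alone, with TNFRSF10B at 0.97 ± 0.21 and FAS at 2.39 ± 0.60. The library labelled siDDX17 replicate 1 moved with this list, with a mean of 1.93 above siCtrl against 0.33 and 0.32 in replicates 2 and 3. The median of the list without it was 0.30.

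Targets of TGF-beta and BMP had a median of 0.39 after siDDX17 without RA, with 1 of 22 higher, the nodal antagonist LEFTY2 (1.14 ± 0.24), or 9 adjusted over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.801 with an estimated correlation, fry adjusted p = 0.290). No member of the other 4 called lists passed. Ribosome biogenesis factors had a median of 0.14 (camera adjusted p = 0.0184) and cholesterol genes -0.22 (camera adjusted p = 0.00150). Oligodendrocyte markers stood at -0.43 (camera adjusted p = 0.0134) and epithelial markers at -0.27 (camera adjusted p = 0.0111). All 4 had adjusted p = 0.801 with an estimated correlation. Their medians without the library labelled siDDX17 replicate 1 were 0.02, 0.01, -0.19 and -0.11, and that of the TGF-beta and BMP targets 0.13. None of these 4 lists was called without it (camera adjusted p = 0.523, 0.617, 0.278 and 0.271 in that order). Without that library 94 genes passed, 80 of them shared with the 187. Without siCtrl replicates 1, 2 and 3 and siDDX17 replicates 2 and 3 in turn 17, 55, 26, 801 and 821 passed. Replicates 1 and 3 alone gave 21.

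After siDDX17 with RA, 123 genes rose and 100 fell. The majority turned to lower with all 24 libraries in the fit (107 higher, 133 lower) and without siDDX17 replicate 1 (74, 81). BCAN-AS1 (4.34 ± 0.36), TMEM105 (4.03 ± 0.25), the fucosyltransferase gene FUT3 (3.81 ± 0.29), POU2F3, a transcription factor of tuft cells (3.59 ± 0.37), SMIM47 (3.46 ± 0.28) and IFITM10 (2.83 ± 0.22) rose. DDX17 (-2.23 ± 0.14), the thioredoxin reductase gene TXNRD3 (-1.89 ± 0.24), FAM161B (-1.35 ± 0.24), the heparan sulfate proteoglycan SDC4 (-1.34 ± 0.15), SCARA3 (-1.31 ± 0.11) and the DNA repair gene UVSSA (-1.30 ± 0.20) fell. 22 genes rose and 25 fell after siDDX17 in both states, against 0.371 and 0.772 if the calls were independent. Without the library labelled siDDX17 replicate 1 in the fit without RA these were 14 and 19. Camera called ribosomal proteins (median 0.48, camera adjusted p = 2.3e-08), oxidative phosphorylation (0.36, camera adjusted p = 8.1e-05) and HOX genes (0.22, camera adjusted p = 0.0329), each at adjusted p = 0.706 with an estimated correlation. It also called mitotic genes (0.11, camera adjusted p = 0.0433, adjusted p = 0.570 with an estimated correlation), with no member of the 4 lists past the test. Ribosomal proteins stood 1.04 above siCtrl in siDDX17 replicate 1 and -0.08 and 0.27 in replicates 2 and 3. Without that replicate 1 their median was 0.07 and that of oxidative phosphorylation 0.05, and neither was called (camera adjusted p = 0.159 and 0.224). None of the 4 lists kept its call in every leave-out. Leaving out siCtrl replicates 1, 2 and 3 and siDDX17 replicate 3 in turn gave 85, 76, 89 and 87 genes, and replicates 1 and 3 alone 35. More genes passed with no filter, the replicate block, a replicate 2 term or DESeq2.

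Knocking down both helicases without RA changed far more genes: 2928 rose and 3634 fell, 892 and 1400 of them by at least 2-fold. IFITM10 (6.03 ± 0.73, 65.6-fold), the Fc receptor-like FCRL6 (5.82 ± 1.21), NPC1L1, which takes up dietary cholesterol in the gut (5.74 ± 1.02), SMIM47 (5.48 ± 0.59) and BCAN-AS1 (4.84 ± 0.74) had the largest rises. ESPNL (3.78 ± 0.36) and IQSEC3 (1.64 ± 0.17) were among the smallest p. MIR210HG (-2.96 ± 0.39, 7.80-fold lower), the lactate exporter SLC16A3 (-2.56 ± 0.27), the myelin regulator MYRF (-2.56 ± 0.27), RHPN1 (-2.53 ± 0.32), PTPRCAP (-2.49 ± 0.33) and the axonal kinesin KIF1A (-2.40 ± 0.41) fell the most. The kinase AKT1 (-1.76 ± 0.13), TMEM129 (-1.88 ± 0.15) and NAB2, a corepressor of EGR1 (-1.81 ± 0.14), fell with some of the smallest p. The 3 libraries of each group did not overlap for 54.9% of the tested genes, where chance gives 10%. Median GC content was 46.0% among genes that rose and 55.8% among those that fell. Among genes under 1 CPM in siCtrl, 26.1% of those that rose and 10.96% of the others had an expressed gene ending within 10 kb upstream on the same strand. IFITM10 lies after CTSD and SMIM47 after C19orf48P. Replicates 1 and 3 alone gave 5769 genes, and the replicate block 8705.

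Targets of p53 rose in 28 of 32 cases after the double knockdown without RA and fell in 1, with a median of 1.44 (camera adjusted p = 1.4e-10, adjusted p = 0.682 with an estimated correlation, fry adjusted p = 0.0129). The proapoptotic BAX (1.13 ± 0.16), the death receptor TNFRSF10B (1.47 ± 0.22) and CCNG1 (0.67 ± 0.10) rose, and the DNA repair gene XPC fell (-1.22 ± 0.18). Cholesterol synthesis and uptake genes fell in 21 of 24 cases, with a median of -0.85 (camera adjusted p = 2.1e-08, adjusted p = 0.682 with an estimated correlation, fry adjusted p = 0.00919). MVD (-1.03 ± 0.13), LSS (-1.59 ± 0.21), MVK (-1.35 ± 0.23) and HMGCS1 (-0.95 ± 0.17), all enzymes of the pathway, were among them. TGF-beta and BMP targets rose in 15 of 22 (0.68, camera adjusted p = 1.1e-04, adjusted p = 0.682 with an estimated correlation, fry adjusted p = 0.0193). The matricellular genes CCN2 (2.94 ± 0.46), THBS1 (2.36 ± 0.41) and CCN1 (2.46 ± 0.44) were among them. Immediate early and nuclear noncoding genes, which also track RNA handling, rose in 10 of 14 (0.94, camera adjusted p = 8.7e-06, adjusted p = 0.682 with an estimated correlation, fry adjusted p = 0.00919), with FOS at 1.68 ± 0.21 and EGR1 at 1.69 ± 0.23. Replication-dependent histone genes rose in 7 of 13 (0.83, camera adjusted p = 0.00621, adjusted p = 0.682 with an estimated correlation, fry adjusted p = 0.00919), led by H2BC21 (1.88 ± 0.19) and H2AC6 (1.43 ± 0.18). Histone messages of this kind normally lack a poly(A) tail, so these counts may not follow total histone RNA.

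Camera called 5 further lists after the double knockdown without RA. Amino acid and ER stress genes rose in 17 and fell in 6 of 33 (camera adjusted p = 0.00734, adjusted p = 0.682 with an estimated correlation), with MTHFD2 at 0.97 ± 0.16 and ATF4 at 0.63 ± 0.12. Ribosome biogenesis factors rose in 14 and fell in 2 of 37 (camera adjusted p = 4.6e-04, adjusted p = 0.682 with an estimated correlation). Ribosomal proteins rose in 10 of 55, 1 adjusted over the list alone (camera adjusted p = 1.2e-04, adjusted p = 0.753 with an estimated correlation). DNA replication genes fell in 13 and rose in 4 of 34 (camera adjusted p = 0.0291, adjusted p = 0.699 with an estimated correlation), with the helicase subunits CDC45 (-1.19 ± 0.14) and MCM5 (-1.32 ± 0.16) lower. The DNA replication call was lost in 1 of 6 fits with 1 library left out (camera adjusted p = 0.112). Oligodendrocyte lineage markers fell in 6 of 7 (-1.05, camera adjusted p = 0.00638, adjusted p = 0.682 with an estimated correlation), including MYRF and CSPG4 (-2.22 ± 0.42). The pluripotency list did not pass (6 rose and 4 fell of 24, camera adjusted p = 0.593). Within it the telomerase gene TERT fell (-1.24 ± 0.15) and FOXD3 rose (0.88 ± 0.14). Other DEAD-box helicases rose in 6 and fell in 5 of 26 (camera adjusted p = 0.451), with DDX50 2.00-fold lower (SE 0.120 on the log2 scale) and DDX41 at 0.81 ± 0.13.

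The double knockdown with RA raised 1697 genes and lowered 2500, 616 and 908 of them by at least 2-fold. BCAN-AS1 (6.69 ± 0.33, 103-fold), POU2F3 (6.20 ± 0.32), FUT3 (4.84 ± 0.28), NPC1L1 (4.80 ± 0.23), SMIM47 (4.72 ± 0.27) and TMEM105 (4.67 ± 0.24) had the largest rises. MIR130AHG (2.30 ± 0.11) was among the smallest p. The ligand WNT6 (-2.58 ± 0.40, 5.98-fold lower), the proteoglycan biglycan gene BGN (-2.14 ± 0.25), TAX1BP3 (-2.11 ± 0.45), the protease HTRA3 (-2.11 ± 0.23), REEP6 (-2.08 ± 0.33) and the Wnt antagonist SOST (-2.06 ± 0.26) fell the most. SCARA3 (-1.70 ± 0.12), the mitochondrial isocitrate dehydrogenase IDH2 (-1.62 ± 0.11) and the matrix gene EMILIN3 (-2.04 ± 0.15) fell with some of the smallest p. The groups did not overlap for 48.3% of the tested genes, again against 10% by chance. Median GC content was 47.5% among genes that rose and 56.3% among those that fell. An expressed gene ended within 10 kb upstream on the same strand for 33.1% of the genes that rose from under 1 CPM and 10.8% of the other genes under 1 CPM. SMIM47 and POU2F3, which lies after OAF, were among the former. 2701 genes passed without double-knockdown replicate 3, and replicates 1 and 3 alone gave 2364.

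Cholesterol genes fell in 19 of 24 cases after the double knockdown with RA (median -0.92, camera adjusted p = 3.1e-13, adjusted p = 9.4e-04 with an estimated correlation). DHCR7 (-1.15 ± 0.11), FDFT1 (-0.99 ± 0.10) and the sterol sensor INSIG1 (-1.04 ± 0.10) were among them. Interferon-stimulated genes fell in 11 of 30 and rose in 1 (-0.63, camera adjusted p = 0.00172, adjusted p = 0.0467 with an estimated correlation). The antiviral OAS3 (-1.91 ± 0.30) and MX1 (-1.01 ± 0.17) fell and the RNA sensor RIGI (1.08 ± 0.21) rose. HOX genes rose in 15 of 29 (0.48, camera adjusted p = 6.2e-07, adjusted p = 0.273 with an estimated correlation, fry adjusted p = 0.00137), with HOXA2 (1.48 ± 0.16) and HOXD4 (1.35 ± 0.20). Neural progenitor markers rose in 8 and fell in 1 of 25 (camera adjusted p = 0.0186, adjusted p = 0.410 with an estimated correlation, fry adjusted p = 0.00283), with SOX21 (1.51 ± 0.13) and NR2F1 (0.59 ± 0.10) higher and nestin, NES (-1.01 ± 0.18), lower. REST targets fell in 9 of 32 (camera adjusted p = 0.00980, adjusted p = 0.273 with an estimated correlation, fry adjusted p = 0.00152), including CHGB (-0.91 ± 0.13) of secretory granules and the neurotrophin BDNF (-0.80 ± 0.12). DNA replication genes fell in 10 and rose in 1 of 34 (camera adjusted p = 0.0322, adjusted p = 0.273 with an estimated correlation, fry adjusted p = 2.4e-04), with MCM5 at -1.35 ± 0.14 and E2F1 at -1.03 ± 0.15. Some fits with 1 library left out ended the calls of neural progenitor markers (2 of 6, highest camera adjusted p = 0.0642) and of DNA replication genes (2 of 6, highest camera adjusted p = 0.0616). Targets of p53 rose in 8 and fell in 2 of 32 (0.34, camera adjusted p = 0.01002, adjusted p = 0.306 with an estimated correlation, fry adjusted p = 0.00360), with the cell cycle inhibitor CDKN1A (0.75 ± 0.14) higher and XPC (-1.22 ± 0.14) lower. Neuronal genes fell in 5 of 40 and none rose, without passing as a list (camera adjusted p = 0.405). Immediate early and nuclear noncoding genes rose in 4 and fell in 2 of 14 (camera adjusted p = 0.297).

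**Figure D2:**
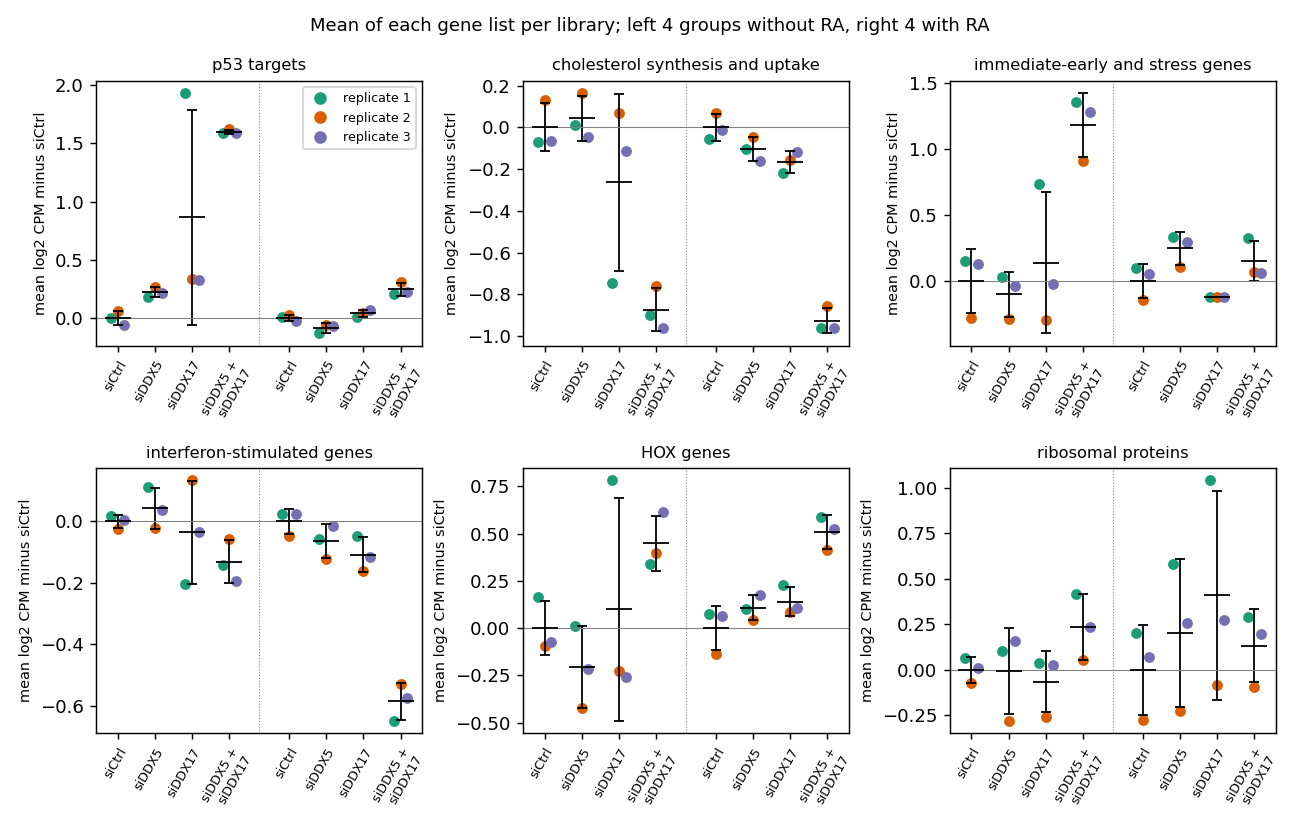
Mean log2 CPM of 6 gene lists in each library, relative to the siCtrl mean of the same state; bars give mean ± SD of the 3 libraries of a group.

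The double knockdown moved many genes alike in the 2 states. Of 15879 genes tested in both, 939 rose in both (254 if the calls were independent), 1793 fell in both (513) and 48 moved in opposite directions. The log2 fold changes correlated across genes with r = 0.72. The 2 states share no library, so this overlap does not come from a shared control. Within a state, 57 of the 58 genes that rose and 129 of the 129 that fell after siDDX17 without RA moved the same way after the double knockdown, as did 120 of 123 and 96 of 100 with RA. Without the library labelled siDDX17 replicate 1, 28 of 31 and 61 of 63 did so without RA, and 2 genes moved in opposite directions. Those comparisons share the siCtrl libraries. Simulated data without any effect gave r = 0.50 and 0.49 between them. The data gave 0.87 (0.55 without the library labelled siDDX17 replicate 1, simulated 0.42) and 0.62. The covariance was 0.378 and 0.191 against 0.0463 and 0.0438 simulated, and no simulated gene was called in both. Without that library the covariance without RA was 0.176 against 0.0378.

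**Figure D3:**
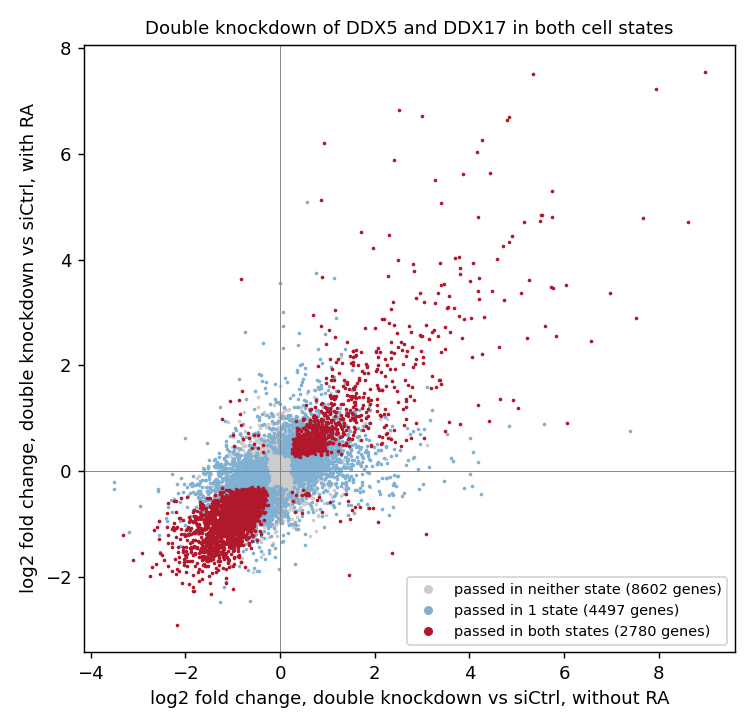
Log2 fold change of each gene after the double knockdown without RA and with RA, coloured by the state or states in which it passed the test.

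Whether RA altered a response was tested as an interaction in the fit of all 24 libraries. After the double knockdown 212 genes responded more positively with RA and 231 less, among 18882 tested. EPHA8, an ephrin receptor (4.44 ± 0.34), TNFRSF8, which encodes CD30 (4.26 ± 0.31), CCDC88B (2.77 ± 0.35), RHOF (2.66 ± 0.32) and SOX21 (2.31 ± 0.18) lay on the positive side. The contractile gene ACTA2 (-4.22 ± 0.75), the antiproliferative BTG2 (-4.07 ± 0.88), H2BC21 (-2.58 ± 0.25), the immediate early EGR3 (-3.94 ± 0.43) and the neuronal calcium sensor VSNL1 (-2.38 ± 0.27) lay on the negative side. ACTG2 and ANGPTL1 also passed, from 0 and 2.00 counts in siCtrl without RA. ACTG2 had means of 0 and 0.235 CPM in siCtrl and double-knockdown cells without RA and 11.6 and 7.58 CPM with RA. ANGPTL1 had 0.0544, 1.09, 15.1 and 12.4 CPM in the same order. Leaving out any library except siCtrl replicate 2 without RA (377) gave 180 to 253 genes. The libraries so left out were siCtrl replicates 1 and 3 and all 3 double-knockdown replicates without RA, and all 6 siCtrl and double-knockdown libraries with RA. Replicates 1 and 3 alone gave 59, and 993 passed without the library labelled siDDX17 replicate 1, which belongs to the fit but not to the groups compared.

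By list, the response of p53 targets to the double knockdown was lower with RA than without, by a median of -1.11, with 8 of 32 past the test and 23 adjusted over the list alone (camera adjusted p = 2.4e-20, adjusted p = 0.0960 with an estimated correlation, fry adjusted p = 0.0110). The kinase PLK2 (-3.66 ± 0.70) and FAS (-2.57 ± 0.62) were among them. Smooth muscle and fibroblast markers (5 of 15 lower, median -0.93, camera adjusted p = 2.1e-07, adjusted p = 0.0960 with an estimated correlation, fry adjusted p = 0.00725) also had a lower response. So did TGF-beta and BMP targets (6 of 23, -0.49, camera adjusted p = 5.8e-10, adjusted p = 0.0960 with an estimated correlation, fry adjusted p = 0.00949), with CCN2 at -3.29 ± 0.49. Immediate early and nuclear noncoding genes (6 of 14, -0.94, camera adjusted p = 1.5e-09, adjusted p = 0.0960 with an estimated correlation) and replication-dependent histones (2 of 13, -0.82, camera adjusted p = 6.9e-06, adjusted p = 0.0960 with an estimated correlation) did the same, with EGR1 at -2.37 ± 0.30. Interferon-stimulated genes (3 of 31, -0.21, camera adjusted p = 0.0205, adjusted p = 0.0960 with an estimated correlation) also stood lower, with TRIM22, an antiviral ubiquitin ligase, at -2.36 ± 0.41. As a list, interferon-stimulated genes fell after the double knockdown with RA, so this lower value need not be a smaller response. Lower responses were also called for neural crest markers (-0.81, camera adjusted p = 0.00554, adjusted p = 0.0960 with an estimated correlation) and trophoblast markers (-1.28, camera adjusted p = 0.0128, adjusted p = 0.141 with an estimated correlation). Wnt targets (-0.34, camera adjusted p = 0.0191, adjusted p = 0.221 with an estimated correlation) and stress genes (-0.27, camera adjusted p = 0.00297, adjusted p = 0.141 with an estimated correlation) were called in that direction too. The same holds for extracellular matrix genes (-0.19, camera adjusted p = 0.0350, adjusted p = 0.614 with an estimated correlation) and ribosome biogenesis factors (-0.17, camera adjusted p = 0.00898, adjusted p = 0.406 with an estimated correlation). Of these, extracellular matrix genes (5 of 12, highest camera adjusted p = 0.153) and Wnt targets (1 of 12, highest camera adjusted p = 0.0952) lost their call in fits with 1 library left out. Only oligodendrocyte markers responded more positively (0.88, camera adjusted p = 0.00150, adjusted p = 0.181 with an estimated correlation).

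For the single knockdowns 1 gene or none passed the interaction test with RA in this fit. After siDDX17 only CCDC88B passed (2.42 ± 0.36, adjusted p = 0.0142 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). 2171 of 18882 genes had an unadjusted p under 0.05. DESeq2 called 43, a fit with no filter 434 and the replicate block 542, so a wider response to siDDX17 is not ruled out. Targets of p53 had a median difference of -1.002 (camera adjusted p = 6.5e-10, adjusted p = 0.746 with an estimated correlation) and -0.30 without the library labelled siDDX17 replicate 1. TGF-beta and BMP targets stood at -0.39 (camera adjusted p = 1.6e-04, adjusted p = 0.746 with an estimated correlation) and -0.08 without it, where they were not called (camera adjusted p = 0.166). Ribosomal proteins (0.52, camera adjusted p = 6.5e-10, adjusted p = 0.746 with an estimated correlation) and oxidative phosphorylation genes (0.38, camera adjusted p = 2.6e-04, adjusted p = 0.746 with an estimated correlation) were called on the positive side, with no member past the test. Without siDDX17 replicate 1 with RA, which stands apart for ribosomal proteins, their medians were 0.15 (camera adjusted p = 0.0171) and 0.11 (camera adjusted p = 0.0894, not called). Leaving out siCtrl replicate 1 in either state or siCtrl replicate 2 with RA gave 0 genes. Leaving out siCtrl replicate 3 and siDDX17 replicates 1, 2 and 3 without RA gave 2, 2, 34 and 29. After siDDX5 edgeR's quasi-likelihood test called 0 genes, DESeq2 called 1, and 474 had an unadjusted p under 0.05. CBLN1 (0.82 ± 0.17) and SLC13A3 (0.96 ± 0.20) had the smallest p on the positive side. Camera called 7 lists there with no member past the test. They include p53 targets (-0.33, camera adjusted p = 0.00125, adjusted p = 0.800 with an estimated correlation) and ribosomal proteins (0.19, camera adjusted p = 7.9e-04, adjusted p = 0.810 with an estimated correlation). Replication-dependent histones (0.31, camera adjusted p = 0.0121, adjusted p = 0.545 with an estimated correlation) and immediate early and nuclear noncoding genes (0.28, camera adjusted p = 0.0121, adjusted p = 0.602 with an estimated correlation) were called as well. The other 3 were neural progenitor markers (0.14, camera adjusted p = 0.0469, adjusted p = 0.545 with an estimated correlation), stress genes (-0.11, camera adjusted p = 0.0469, adjusted p = 0.545 with an estimated correlation) and REST targets (0.12, camera adjusted p = 0.0469, adjusted p = 0.545 with an estimated correlation). Of these 7 only p53 targets kept their call in every leave-out. Replicates 1 and 3 alone gave 0 genes for siDDX17 and 0 for siDDX5.

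Compared directly without RA, 21 genes were higher and 42 lower after siDDX17 than after siDDX5. The majority turned to higher with no filter (567 higher, 336 lower) and without siDDX17 replicate 2 (114, 81) or 3 (116, 77). DDX5 (1.61 ± 0.20) and DDX17 (-1.71 ± 0.21) differed as the siRNAs target them. SMIM47 (4.78 ± 0.69), IFITM10 (3.83 ± 0.69), ESPNL (2.26 ± 0.35), LEMD1 (1.92 ± 0.33), IL16 (35.4-fold (counting interval 11.8 to 174)) and VGF (0.91 ± 0.11) were higher. TRAPPC6A (-1.29 ± 0.19), D2HGDH (-1.24 ± 0.17), ASB16-AS1 (-1.16 ± 0.20), TMEM129 (-1.16 ± 0.14) and the lipid kinase PI4K2B (-0.99 ± 0.12) were lower. Neuronal genes (0.13, camera adjusted p = 0.0161, adjusted p = 0.282 with an estimated correlation, fry adjusted p = 0.0173), with MAP2 at 0.86 ± 0.16, neural progenitor markers (0.16, camera adjusted p = 0.00236, adjusted p = 0.391 with an estimated correlation) and neural crest markers (0.39, camera adjusted p = 0.0161, adjusted p = 0.282 with an estimated correlation) had higher medians. So did p53 targets (0.72, camera adjusted p = 8.0e-08, adjusted p = 0.626 with an estimated correlation) and TGF-beta and BMP targets (0.57, camera adjusted p = 2.6e-06, adjusted p = 0.621 with an estimated correlation), whose medians without that library were 0.10 and 0.15. Of the 7 further called lists, REST targets (0.21, camera adjusted p = 0.0230, adjusted p = 0.621 with an estimated correlation) and ribosome biogenesis (0.12, camera adjusted p = 0.00611, adjusted p = 0.662 with an estimated correlation) were higher. So were splicing factors (0.07, camera adjusted p = 0.0328, adjusted p = 0.662 with an estimated correlation) and immediate early and nuclear noncoding genes (0.28, camera adjusted p = 0.0494, adjusted p = 0.791 with an estimated correlation). Cholesterol genes (-0.26, camera adjusted p = 2.6e-06), oligodendrocyte markers (-0.24, camera adjusted p = 0.0230) and epithelial markers (-0.17, camera adjusted p = 0.00868) were lower, each at adjusted p = 0.626 with an estimated correlation. Without that library camera called 7 lists. Immediate early and nuclear noncoding genes then had a median of -0.07, the other direction (camera adjusted p = 0.847). Ribosome biogenesis (0.672), splicing factors (0.370), cholesterol (0.262), oligodendrocyte (0.703) and epithelial genes (0.371) lost their camera call at the adjusted p given. Only neural progenitor markers, p53 targets and TGF-beta and BMP targets kept their camera call in every leave-out. Leaving out siDDX5 replicates 1, 2 and 3 and siDDX17 replicates 2 and 3 in turn gave 4, 29, 7, 195 and 193 genes, and replicates 1 and 3 alone 0.

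With RA, 76 genes were higher and 64 lower after siDDX17 than after siDDX5. Beside DDX5 (1.38 ± 0.14) and DDX17 (-2.19 ± 0.14), TMEM105 (3.73 ± 0.24), FUT3 (3.65 ± 0.29), BCAN-AS1 (2.91 ± 0.31), IL16 (2.65 ± 0.27) and IFITM10 (2.43 ± 0.22) were higher. TXNRD3 (-1.85 ± 0.24), the pseudogene GPR199P (-1.82 ± 0.20), SCARA3 (-1.30 ± 0.11) and 4 members of the immediate early list, FOS (-1.06 ± 0.16), FOSB (-1.89 ± 0.29), EGR1 (-0.97 ± 0.16) and EGR2 (-1.31 ± 0.22), were lower (4 of 14, camera adjusted p = 0.0149, adjusted p = 0.452 with an estimated correlation). Among the other called lists, mitotic genes (0.14, camera adjusted p = 7.7e-04, adjusted p = 0.160 with an estimated correlation), p53 targets (0.17, camera adjusted p = 0.0388, adjusted p = 0.452 with an estimated correlation) and stress genes (0.11, camera adjusted p = 0.0241, adjusted p = 0.452 with an estimated correlation) had higher medians. So did oxidative phosphorylation (0.23, camera adjusted p = 0.0176, adjusted p = 0.771 with an estimated correlation) and ribosomal proteins (0.26, camera adjusted p = 0.00395, adjusted p = 0.807 with an estimated correlation). These 2 directions rest on single libraries: without siDDX17 replicate 1 both turned lower (camera adjusted p = 0.670 and 0.0826), and without siDDX5 replicate 2 oxidative phosphorylation lost its call (camera adjusted p = 0.816) and ribosomal proteins turned lower (0.944). Proneural factors (-0.24, camera adjusted p = 0.00395, adjusted p = 0.452 with an estimated correlation) and REST targets (-0.08, camera adjusted p = 0.0365, adjusted p = 0.452 with an estimated correlation) had lower ones. Only mitotic genes kept their camera call in every leave-out. Without siDDX5 replicates 1, 2 and 3 and siDDX17 replicates 2 and 3 in turn 74, 44, 48, 93 and 46 genes passed, with replicates 1 and 3 alone 16. With the replicate number as a block, used for the same reason, 745 passed, 292 higher and 453 lower, so the majority turned from higher to lower, as it did with DESeq2 (146 higher, 213 lower).

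The effect of both siRNAs was also set against the sum of the single effects on the log2 scale. Without RA, 1 gene passed, the histone gene H2BC21, which lay above the sum (2.60 ± 0.28, adjusted p = 0.00633 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). As for the histone list, its counts in poly(A) libraries may not follow its total RNA. 1652 genes had an unadjusted p under 0.05. FOS stood at 2.04 ± 0.29. The library labelled siDDX17 replicate 1 weighs on this sum. Without it 708 genes lay above and 1221 below it. 3 genes passed without double-knockdown replicate 2. Camera called 11 lists. Above the sum were p53 targets (0.21, 0.98 without that library, camera adjusted p = 0.00276, adjusted p = 0.719 with an estimated correlation) and immediate early and nuclear noncoding genes (0.85, camera adjusted p = 7.5e-12, adjusted p = 0.399 with an estimated correlation). So were replication-dependent histones (0.61, camera adjusted p = 1.1e-07, adjusted p = 0.272 with an estimated correlation) and ribosomal proteins (0.30, camera adjusted p = 3.7e-12, adjusted p = 0.617 with an estimated correlation). Also above it were TGF-beta and BMP targets (0.29, camera adjusted p = 0.00776, adjusted p = 0.693 with an estimated correlation), ribosome biogenesis (0.13, camera adjusted p = 0.00159, adjusted p = 0.628 with an estimated correlation) and splicing factors (0.14, camera adjusted p = 0.00193, adjusted p = 0.617 with an estimated correlation). The last 2 above it were neural progenitor markers (0.10, camera adjusted p = 0.0409, adjusted p = 0.617 with an estimated correlation) and astroglia (0.15, camera adjusted p = 0.0490, adjusted p = 0.399 with an estimated correlation). Cholesterol genes (-0.67, camera adjusted p = 7.5e-12, adjusted p = 0.617 with an estimated correlation) and DNA replication genes (-0.19, camera adjusted p = 0.00290, adjusted p = 0.617 with an estimated correlation) lay below it. Leaving out 1 library at a time ended the calls of p53 targets (2 of 12, highest camera adjusted p = 0.208), TGF-beta and BMP targets (2 of 12, highest camera adjusted p = 0.111), neural progenitor markers (5 of 12, highest camera adjusted p = 0.0791) and astroglia (10 of 12, highest camera adjusted p = 0.111) in the number of fits given. Replicates 1 and 3 alone gave 1 gene.

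With RA, 89 genes lay above and 561 below the sum of the single effects. How far the lower side outweighs depends on the fit, as DESeq2 gave 374 above and 1143 below, a replicate 2 term 858 and 1686 and the replicate block 2388 and 2883. NPC1L1 (3.81 ± 0.38), TNFRSF8 (4.33 ± 0.60), the phosphodiesterase PDE4C (2.44 ± 0.43), FERMT3 (2.24 ± 0.49) and the dynein DNAH2 (2.05 ± 0.37) lay above. TMEM141 (-2.28 ± 0.50), the matrix gene EMILIN1 (-2.26 ± 0.25), COMTD1 (-2.14 ± 0.53), WNT4 (-1.67 ± 0.17) and TMEM98 (-1.31 ± 0.15) lay below. Cholesterol genes lay below the sum in 9 of 24 cases (-0.71, camera adjusted p = 8.5e-09, adjusted p = 0.00402 with an estimated correlation), including FDFT1 (-0.88 ± 0.14) and MVK (-1.18 ± 0.20). Smooth muscle and fibroblast markers (2 of 14, -0.71, camera adjusted p = 0.00993, adjusted p = 0.547 with an estimated correlation) and oxidative phosphorylation (4 of 41, -0.47, camera adjusted p = 0.00739, adjusted p = 0.823 with an estimated correlation) were called below it. So were ribosomal proteins (0 of 55, -0.59, camera adjusted p = 7.0e-04, adjusted p = 0.849 with an estimated correlation), DNA replication genes (3 of 34, -0.22, camera adjusted p = 0.00865, adjusted p = 0.318 with an estimated correlation) and REST targets (-0.29, camera adjusted p = 0.0397, adjusted p = 0.454 with an estimated correlation). HOX genes (2 of 29, 0.17, camera adjusted p = 0.0215, adjusted p = 0.707 with an estimated correlation) and p53 targets (2 above and 1 below of 32, 0.32, camera adjusted p = 0.00520, adjusted p = 0.318 with an estimated correlation) were called above it. The same was found for microRNA processing genes (0.43, camera adjusted p = 0.00739, adjusted p = 0.454 with an estimated correlation). In siDDX17 replicate 1, part of that sum, ribosomal proteins stood apart (1.04 above siCtrl). Without it they had a median of -0.18 and oxidative phosphorylation -0.16, and neither was called (camera adjusted p = 0.130 and 0.0823). HOX genes and REST targets also lost their call in some leave-outs. Leaving out siCtrl replicates 1, 2 and 3, siDDX5 replicates 1 and 3, siDDX17 replicate 2 and double-knockdown replicates 1, 2 and 3 in turn gave 156, 294, 111, 205, 417, 1082, 283, 176 and 114 genes, and replicates 1 and 3 alone 0.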

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

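The tests of neighbouring reads and the first test of GC content were chosen before their results were seen, and the tests of the second GC value, of the library labelled siDDX17 replicate 1, of the p53 targets with and without RA and of other splits of the libraries only after. The results below were singled out because a knockdown effect differed between cells with and without RA in the test of that difference itself.

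The interaction with RA passed for 443 genes after the double knockdown and for 1 after siDDX17, CCDC88B (2.42). After the double knockdown the named genes on the positive side were EPHA8 (4.44), TNFRSF8 (4.26), CCDC88B (2.77), RHOF (2.66) and SOX21 (2.31). Those on the negative side were ACTA2 (-4.22), BTG2 (-4.07), EGR3 (-3.94), PLK2 (-3.66), CCN2 (-3.29), H2BC21 (-2.58), FAS (-2.57), VSNL1 (-2.38), EGR1 (-2.37) and TRIM22 (-2.36). ACTG2 (-5.35) and ANGPTL1 (-4.35) had 0 and 2.00 counts in siCtrl without RA, so these fitted values depend on the prior count. Of the lists called by camera for the double knockdown, the median differences were -1.11 for p53 targets, -0.94 for immediate early and nuclear noncoding genes, -0.93 for smooth muscle and fibroblast markers, -0.82 for histones, -0.81 for neural crest, -1.28 for trophoblast and -0.49 for TGF-beta and BMP targets. They were -0.34 for Wnt targets, -0.27 for stress genes, -0.21 for interferon-stimulated genes, -0.19 for extracellular matrix, -0.17 for ribosome biogenesis and 0.88 for oligodendrocyte markers. For siDDX17 they were -1.002 for p53 targets, -0.39 for TGF-beta and BMP targets, 0.38 for oxidative phosphorylation and 0.52 for ribosomal proteins, and without the library labelled siDDX17 replicate 1 without RA -0.30, -0.08, 0.36 and 0.56. The last 2 depend more on siDDX17 replicate 1 with RA, where ribosomal proteins stood 1.04 above siCtrl against -0.08 and 0.27 in replicates 2 and 3. Without it they were 0.11 (camera adjusted p = 0.0894, not called) and 0.15 (camera adjusted p = 0.0171). For siDDX5 the median differences were -0.33 for p53 targets, 0.19 for ribosomal proteins, 0.31 for histones, 0.28 for immediate early and nuclear noncoding genes, 0.14 for neural progenitor markers, 0.12 for REST targets and -0.11 for stress genes. Of these lists none was called with an estimated correlation.

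Targets of p53 rose less after the double knockdown with RA than without. A weaker knockdown with RA is a candidate explanation: DDX17 kept 3.44 points more of its control level with RA while DDX5 kept -1.11 points, and neither difference passed the interaction test, so it cannot be told apart from an equal knockdown. A higher starting level with RA may also narrow the response: the targets were higher with RA in siCtrl by a median of 0.607 (quartiles 0.359 to 1.77), below the -1.11 by which the response was lower, but within the spread of the members, so this stays open too. A different response of RA-treated cells stays open, untested, as does a batch that coincides with RA.

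The library labelled siDDX17 replicate 1 without RA had low DDX5, DDX17 above the rest of its group and p53 targets at the level of the double knockdown or above. A swap with a double-knockdown library is excluded, since the highest DDX5 in that group was 190.1 CPM, far under the 526.6 CPM that a displaced siDDX17 library would show. This library's DDX17, 269.2 CPM, lay above all others of siDDX17 and double knockdown. This argues against a mixture of material like theirs. The p53 target mean of the library, 1.93, lay above the 1.62 of the highest double-knockdown library. This argues against a mixture of control material with material like these double-knockdown libraries. Material with a weaker knockdown or stronger p53 response is not covered. DDX5 and DDX17 stood at 48.7% and 51.5% of control in this library. A wrong label on a sample from outside these groups and a response of that culture were not tested and stay open.

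What rose and fell after the double knockdown differed in GC content and in genome neighbours. GC bias of the libraries cannot be excluded as a contributor, since within groups the correlation of a replicate with GC reached -0.299 without RA, as large as that of the effect itself (-0.276), and with RA ranged from -0.414 to 0.461, larger than that of the effect (-0.252); that many of the calls are made again after a correction says nothing of it, because the correction removes the GC difference by construction. As the whole cause of the calls it is excluded, as 88.5% of the genes called without RA were called in the same direction after each library's GC and length trend was removed with a replicate block (81.3% with no block), and 88.6% with RA with no block. Reads running on from an expressed gene upstream may be a source of part of the genes raised from under 1 CPM. A same-strand neighbour ending within 10 kb was more frequent among them, with odds ratios of 2.86 (2.08 to 3.95) without RA and 4.07 (3.05 to 5.43) with RA. Opposite-strand ratios were 0.852 (0.524 to 1.35) and 0.478 (0.283 to 0.771), a depletion with RA. Promoter activity of the genes themselves was not tested, and raw reads were not analysed.

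The libraries compared were also regrouped, to see how often another split gave as many genes. Groups of 3 against 3 make 10 splits, too few for a share under 0.05: 1 of 10, the real split, gave as many genes for siDDX5 (2 genes without RA, 2 with RA), siDDX17 (187, 223), the double knockdown (6562, 4197), siDDX17 against siDDX5 without RA (63) and RA itself (11490), and the highest other split gave 0 genes for each of these. For siDDX17 against siDDX5 with RA, 2 of 10 splits did, again too few: siDDX17 replicate 1 with siDDX5 replicates 1 and 3, against siDDX17 replicates 2 and 3 with siDDX5 replicate 2, gave 2879 genes where the real split gave 140, which points to a structure of the samples other than the siRNA, and the replicate block gave 745 for the real split. For departures from additivity, 5 of 40 splits without RA (real 1, highest other 5031) and 3 of 40 with RA (real 650, highest other 2311) gave as many, so chance is not excluded; these regroupings mix real knockdown effects, a structure that by itself calls many genes. For the siDDX5 interaction with RA the real count was 0, so every split gives as many (22 of 22 splits, highest other 0) and the splits decide nothing. For siDDX17 2 of 22 splits gave as many (real 1, highest other 6), so chance is not excluded. For the double knockdown only the real split did, 1 of 22 (real 443, highest other 151). That is the smallest share these splits can give. The other splits mix double-knockdown with control libraries, which widens the spread within their groups, so chance is not excluded here either. In fits of the 4 compared groups alone, the real split gave 1545 genes for the double knockdown and the highest of the others 682, while for siDDX5 another split gave 2366 and the real one 0, which again points to a structure of the samples.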

How the results depend on the processing

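The tests with a replicate 2 term, with replicates 1 and 3 alone and without the library labelled siDDX17 replicate 1 were chosen only after the results were seen; the other alternatives were planned. With 3 libraries per group and at most 16395091 counts each, many 2-fold changes are missed (see the simulation), so counts of small responses depend on the noise estimate. The counts for RA (11490) and for the double knockdown without RA (6562) stayed within 1.5 times under every alternative run, leave-outs included. DESeq2 size factors and a filter at a mean count of 10 or more moved no count of genes by more than 1.5 times; the size factors shifted the median log2 fold change by at most 0.0223. Of 3581 values for genes named in the text, 3338 kept direction and side of the threshold, 222 no longer passed, 21 newly passed and 0 reversed; of 1603 values for called lists, 1270 kept both, 329 no longer passed and 4 reversed. Where a count below moved, the cause was not tested, except that fewer libraries or fewer tested genes are part of some settings.

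Counts that moved by more than 1.5 times were as follows. With no filter: siDDX5 without RA 10 (from 2), siDDX17 1597 without RA (from 187) and 487 with RA (from 223), siDDX17 against siDDX5 903 (from 63) and 275 (from 140), departures from additivity 323 (from 1) and 1261 (from 650), interactions with RA 5 for siDDX5 (from 0), 434 for siDDX17 (from 1) and 673 for the double knockdown (from 443). With the replicate block: siDDX17 998 and 2458, siDDX17 against siDDX5 327 and 745, additivity 418 and 5271 (the latter 2388 above the sum and 2883 below), siDDX5 with RA 13, double knockdown with RA 7097, interactions 2, 542 and 1512, and genes moved alike in both states by the double knockdown 4606 (from 2732); the block moved no other count by as much. With the replicate 2 term: siDDX17 1182 and 747, siDDX17 against siDDX5 351 and 372, additivity 410 and 2544, siDDX5 with RA 5, interactions 26 for siDDX17 and 1114 for the double knockdown. With replicates 1 and 3 alone: siDDX5 0 and 0, siDDX17 21 and 35, siDDX17 against siDDX5 0 and 16, double knockdown with RA 2364, additivity with RA 0, interactions 0 and 59, alike in both states 1558. With DESeq2: siDDX5 6 and 16, siDDX17 739 and 521, siDDX17 against siDDX5 308 and 359, additivity 41 and 1517, interactions 1, 43 and 699. With only the compared groups in the fit: siDDX17 6 and 33, siDDX17 against siDDX5 0 and 10, siDDX5 with RA 1, interactions 0 for siDDX17 and 1545 for the double knockdown. With all 24 libraries in the fit: siDDX17 without RA 754, siDDX5 with RA 4. Without the library labelled siDDX17 replicate 1 the counts were 94 for siDDX17, 1929 for additivity, 2 for the siDDX17 interaction and 993 for the double-knockdown interaction. DDX5 after the double knockdown without RA was 30.9% of control with total counts as library sizes.

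Leaving out each library in turn gave 0 to 1 genes for siDDX5 without RA and 1 with RA, 17 to 821 and 76 to 213 for siDDX17, 2701 to 3153 for the double knockdown with RA, 4 to 195 and 44 to 167 for siDDX17 against siDDX5, 1 to 1929 and 111 to 1082 for additivity, and 0 to 34 and 180 to 377 for the siDDX17 and double-knockdown interactions; these fits hold 1 library less. Lists called by camera, with an estimated correlation and by fry were 4, 0 and 0 for siDDX5 without RA, 6, 0 and 0 for siDDX17, 10, 0 and 15 for the double knockdown, 12, 0 and 2 for siDDX17 against siDDX5 and 11, 0 and 0 for additivity; with RA 8, 0 and 0, 4, 0 and 1, 7, 2 and 13, 8, 0 and 1, and 9, 1 and 7 in the same order. They were 25, 15 and 33 for RA, and 7, 0 and 0, 4, 0 and 0, and 13, 0 and 12 for the interactions of siDDX5, siDDX17 and both. Leave-outs gave 2 to 7 lists for siDDX5 without RA, 7 to 13 for siDDX17 against siDDX5 without RA, 3 to 8, 1 to 5 and 5 to 6 for siDDX5, siDDX17 and siDDX17 against siDDX5 with RA, and 4 to 10 and 4 to 8 for the interactions of siDDX5 and siDDX17. The lists that kept their camera call in every leave-out were 2 of 4 for siDDX5 without RA, 2 of 6 for siDDX17, 9 of 10 for the double knockdown, 3 of 12 for siDDX17 against siDDX5, 7 of 11 for additivity; with RA 1 of 8, 0 of 4, 5 of 7, 1 of 8, 5 of 9 in the same order; 25 of 25 for RA, and 1 of 7, 2 of 4 and 11 of 13 for the interactions. Lists called in siDDX17 against siDDX5 whose direction reversed in a leave-out (camera adjusted p, lowest and highest over the leave-outs) were immediate early and nuclear noncoding genes without RA (0.00283 without siDDX17 replicate 2, 0.847 and reversed without siDDX17 replicate 1), ribosomal proteins with RA (3.4e-11 without siDDX17 replicate 2, 0.944 and reversed without siDDX5 replicate 2, and reversed also without siDDX17 replicate 1, 0.0826) and oxidative phosphorylation with RA (4.9e-06 without siDDX17 replicate 2, 0.816 without siDDX5 replicate 2, and reversed without siDDX17 replicate 1, 0.670). The cause was not tested.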

Other observations

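Which values to show in this part was chosen after the results were seen, and no further tests were run for it. The shares of genes that rose and fell after the double knockdown are given by gene type, and no difference between types was tested. Without RA, 24.3% of 1484 tested genes of types other than protein-coding and pseudogene rose and 10.9% fell, against 17.4% and 25.03% of 13433 protein-coding genes. Pseudogenes, whose reads can come from their parent genes, rose in 9.75% and fell in 3.87% of 1549 cases. Genes without a known type rose in 18.9% and fell in 12.95% of 386 cases. With RA the shares were 17.8% and 6.64% for genes of other types, 8.67% and 16.4% for protein-coding genes, 6.84% and 2.67% for pseudogenes and 10.95% and 9.05% for genes without a known type.

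Several lists that did not pass as a whole held large single changes after the double knockdown. Starting levels are not given and some may lie near the floor. Without RA, the glycolysis regulators PFKFB4 (-1.76 ± 0.17) and PFKL (-1.44 ± 0.20) and the Notch pathway genes LFNG (-1.45 ± 0.16) and NOTCH3 (-1.66 ± 0.23) fell, while the hypoxia-induced peptide gene ADM (2.47 ± 0.36) rose. Interferon-stimulated genes moved both ways, with STAT2 lower (-1.37 ± 0.15) and the RNA sensor RIGI higher (2.28 ± 0.40). With RA, LEFTY1 (4.46 ± 0.34) and CER1 (2.50 ± 0.39), 2 nodal antagonists, rose, as did the Notch ligand DLL4 (2.63 ± 0.47). The Wnt feedback genes NOTUM (-2.13 ± 0.29), NKD1 (-1.35 ± 0.14) and APCDD1 (-1.14 ± 0.13) fell, as did the amino acid transporter SLC7A11 (-1.40 ± 0.18) and the oligodendrocyte lineage genes CSPG4 (-1.66 ± 0.22) and MYRF (-1.28 ± 0.21). The lists themselves gave camera adjusted p = 0.750 for glycolysis and 0.356 for Notch without RA. With RA camera adjusted p was 0.132 for Wnt targets and for endoderm.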
